A study of Manihot esculenta with 24 samples.

How the data were processed

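RNA was extracted with Trizol and libraries were made with Illumina protocols, per the labels' protocols. FastQC and TopHat2 2.0.13 are named in the submitters' processing notes. The quantification tool, the annotation and the genome build are not given in the sources used here. The deposited files hold 1 value per gene and library for 30666 genes. The authors' values were treated as FPKM, a read number scaled by transcript length and library total, a unit read from the values themselves, since neither the headers nor the labels name it. RPKM would not be told apart from it. The sums of a library differed between libraries, from 611321 to 2165161, and the values were not whole numbers. For 159 low genes with ID numbers up to 20000, the smallest value above 0 rose with the ID number (rho 0.699 across genes). Depth was not known. A shared step between low values of 2 libraries was seen in the PEG libraries, in 2.63% to 10.6% of low pairs against the root at 3 h, and in 1.11% to 1.72% of them in the organ libraries, so that no read counts were recovered.

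Gene identifiers were compared with a RefSeq gene table of the M.esculenta_v8 assembly (34312 genes) and 0 matched. The gene lists fixed before the data were examined, HD-Zip genes and cell type markers among them, are defined by product names and were therefore not run. The rule for named genes then allowed at most 2 identifiers that rose and 2 that fell in each comparison, those with the largest fitted change among genes past the threshold that changed the same way in every pair, leaving out genes with a mean below 1 in both sides.

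All tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended prior and robust moderation. A fold change on this scale understates the change of low genes. Genes needed a value of at least 1 in at least 2 libraries of the fit. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene passed with an adjusted p under 0.05 and an absolute log2 change of at least 1. In the PEG series the model held organ and time (6 residual degrees of freedom). For the difference between root and leaves it also held time by root (4 residual degrees of freedom), and the root was assumed to vary like the leaves. In the organ series the model held cultivar and organ (4 residual degrees of freedom). The comparison of root and leaves at 60 days was added after the data were seen. Labels do not show separate plants.

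Gene groups were formed from the genes that passed in one series and tested in the other with camera (preset correlation of 0.01, and again with an estimated one), 88 tests adjusted together. This was chosen after the data were seen. The root changes under PEG and the W14 root have no replicates; there a group's median was set against 10000 random lists of the same size matched on mean expression. The alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, no fold minimum, no block, the 3 leaf positions alone, storage root stages as 1 organ, each organ or library left out, and, added later, removal of a trend against the ID number. Other splits of the libraries were fitted, at most 100 per comparison, and, chosen later, all splits that keep the blocks.

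The fits were tested on simulated data with 200 changed genes. In the data 7572 genes passed for storage root against leaf, so that the adjusted threshold was less strict there than in the simulation. The simulated noise was also independent between genes. The shares and false calls below therefore do not carry over to the real fits. For PEG 24 h against 0 h, run on 25739 genes, 31.3% of genes changed 2-fold, 85.1% of those changed 4-fold and 87.9% of those changed 8-fold were recovered, with 5 false calls. For storage root against leaf, run on 24351 genes, the shares were 0, 10.4% and 34.8% with 0 false calls. For Arg7 against KU50, also on 24351 genes, they were 0, 28.4% and 63.6% with 2 false calls. For the difference between root and leaves, on 25771 genes, they were 0, 0 and 24.2% with 1 false call. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.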

Results

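Transcript levels were measured by RNA sequencing in 24 libraries of cassava (Manihot esculenta), a woody shrub grown for its starchy storage roots. The first series of 12 libraries compared organs of 3 cultivars. It held leaf, stem and root of W14 at 90 days, leaf of KU50 at 90 days, leaf and stem of Arg7 at 90 days, and early, middle and late storage roots of KU50 and Arg7 at 90, 150 and 210 days. The second series of 12 libraries followed KU50 plants of 60 days for 0, 3 and 24 h of treatment with polyethylene glycol (PEG), a polymer that lowers the water potential around the root. The bottom leaf, the full expanded leaf, the folded leaf and the root were sampled at each time. No library without PEG at 3 h or 24 h was used here, so that effects of PEG and of the time since its start are not separated. Each combination of cultivar, organ and time was a single library, so that organs, cultivars or PEG times took the place of replicates in the tests, and the p-values measure how alike a difference was across them, not the spread between plants. Each library listed 30666 genes as FPKM values. Values of at least 1 were listed for 19967 to 21838 genes per library in the organ series and for 21074 to 23853 in the PEG series. Read totals were not among the values used here. The values of a library summed to 611321 to 2165161 in the organ series and to 808794 to 1378818 in the PEG series. The 10 most abundant genes took 26.04% of the sum in the Arg7 leaf and 3.85% in the root at 3 h. The series addresses the expression of HD-Zip genes, a family of plant transcription factors. The files do not pair gene identifiers with names, and HD-Zip genes were not analysed here. Genes are therefore described as groups, each formed from the calls in one series and then measured in the libraries of the other series.

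The organ series asked which genes differ between the storage root and the leaf. Of 24689 genes tested, 3693 were higher in the storage root and 3879 were higher in the leaf (limma, adjusted p under 0.05 and a fold of at least 2). The median difference was 2.1 on the log2 scale among the former and -2.3 among the latter. Of these 7572 genes, 7389 differed the same way in all 6 pairs of a storage root and the leaf of its cultivar. The fit favours genes that differ alike in the cultivars, and 49.7% of all genes tested went the same way in all 6 pairs. The gene cassava4.1_017149m.g had 503 ± 241 FPKM (SD, n = 6) in storage roots and 3.46 ± 3.14 (SD, n = 2) in the leaves of KU50 and Arg7, a log2 difference of 6.85 ± 0.57 (SE, limma adjusted p = 0.000316). The gene cassava4.1_017243m.g had 280 ± 320 FPKM (SD, n = 6) in storage roots and 18300 ± 7220 (SD, n = 2) in those leaves, a log2 difference of -7.5 ± 0.95 (SE, limma adjusted p = 0.000944).

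Root and leaf differed in many of the same genes at 60 days in KU50. This comparison pools 0, 3 and 24 h, so that 2 of the 3 root libraries and 6 of the 9 leaf libraries were PEG-treated. The root held 5166 genes at a higher level than the mean of the 3 leaf positions and 4424 at a lower level, of 25942 tested with limma. Of the 3835 leaf-higher genes of the organ series that were measured in the PEG libraries, 2500 were lower in the 60-day root and 191 were higher, against 685.7 lower genes for independent lists. Their median difference was -1.69 on the log2 scale (camera adjusted p = 2.91e-46, and adjusted p = 0.0686 with an estimated correlation). Of 3596 storage-root-higher genes, 1545 were higher and 126 lower in the 60-day root, with a median of 0.88 (camera adjusted p = 1.89e-15, and adjusted p = 0.229 with an estimated correlation). In the reverse direction, the 4121 genes higher in the 60-day root had a median of 0.96 in the storage root against the leaf (camera adjusted p = 1.59e-15). That was the only one of 88 group tests to pass with an estimated correlation (adjusted p = 0.046), and 41 passed with the preset one. The gene cassava4.1_024521m.g had 1950 ± 1640 FPKM (SD, n = 3, from 425.659 to 3678.29 across the PEG times) in the 60-day root and 1.64 ± 1.17 (SD, n = 9) in the leaves, and cassava4.1_020069m.g had 12.7 ± 0.607 (SD, n = 3) and 3260 ± 1370 (SD, n = 9).

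In the stem, 1757 genes were higher and 1186 lower than in the leaf. The gene cassava4.1_017087m.g had 791 ± 95.4 FPKM (SD, n = 2) in the stems and 12.7 ± 16.4 (SD, n = 2) in the leaves of W14 and Arg7 (log2 difference 7.31 ± 0.98, SE, limma adjusted p = 0.00623). The gene cassava4.1_008148m.g had 2.32 ± 0.653 and 511 ± 489 FPKM in the same organs (SD, n = 2 each, log2 difference -7.13 ± 0.68, SE, limma adjusted p = 0.00429). The stem is sampled in W14 and Arg7 only, and without the Arg7 stem library 655 genes passed. Without cultivars in the model the count was 1314.

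The folded leaf, the youngest position, held 4036 genes at a higher level and 2322 at a lower level than the bottom leaf (limma, 3 libraries each, 1 per PEG time). After quantile normalization 3334 were higher and 2984 lower, and the median difference of all genes was -0.106, against 0.007 before. The gene cassava4.1_025231m.g had 2470 ± 333 FPKM (SD, n = 3) in the folded leaf and 1.98 ± 0.432 (SD, n = 3) in the bottom leaf. The gene cassava4.1_017902m.g had 2.11 ± 1.01 and 502 ± 188 FPKM (SD, n = 3 each). Genes higher in the stem were more often higher than lower in the folded leaf. Of 1678 stem-higher genes measured in the PEG libraries, 1113 were higher in the folded leaf and 28 were lower, against 263.9 higher genes for independent lists, and their median difference was 1.81 on the log2 scale (camera adjusted p = 1.47e-33, and adjusted p = 0.265 with an estimated correlation). Storage-root-higher genes were also more often higher in the folded leaf, 1213 against 190 lower (camera adjusted p = 2.69e-08, and adjusted p = 0.396 with an estimated correlation).

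After 24 h of PEG, 153 genes were higher (raised) and 130 lower (lowered) than at 0 h over the 4 organs, of 25942 tested with limma. Each of the 283 genes moved the same way in all 4 organs. The fit takes the disagreement between organs as its spread, so that this and the like medians per organ follow largely from the selection. Of all 25942 genes tested, 26.1% moved the same way in all 4 organs. The raised genes had a median change of 1.53 on the log2 scale in the bottom leaf, 1.4 in the full expanded leaf, 1.37 in the folded leaf and 1.53 in the root. The lowered genes had medians of -1.33, -1.3, -1.36 and -1.3 in the same order. The gene cassava4.1_009252m.g rose from 2.73 ± 1.93 FPKM at 0 h to 29.2 ± 12.2 at 24 h (SD, n = 4 organs, log2 change 3.08 ± 0.18, SE, limma adjusted p = 0.000546), and it stood at 2.61 ± 1.73 at 3 h. The gene cassava4.1_025331m.g fell from 80.6 ± 82 to 3.54 ± 5.23 FPKM (SD, n = 4 organs, log2 change -4.14 ± 0.63, SE, limma adjusted p = 0.0315). The count rested on which organs were used: 0 to 1 genes passed when a leaf position was left out, 684 when the root was left out, and 0 without organs in the model. Quantile normalization gave 109 genes, of which 81 rose and 28 fell, and 113 passed without the filter on low values.

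After 3 h of PEG no gene passed over the 4 organs, and 1533 of 25942 had an unadjusted limma p under 0.05. That is close to the share of 0.05 that unchanged genes alone would give. The test covers changes shared by the 4 organs and takes their disagreement as its spread. The share therefore does not speak to changes within a single organ. From 3 h to 24 h, 5 genes rose and none fell, among them cassava4.1_009252m.g and cassava4.1_027920m.g, which went from 12.1 ± 4.61 to 113 ± 58.9 FPKM (SD, n = 4 organs, limma adjusted p = 0.0164). In the 3 leaf positions alone, 304 genes were raised and 380 lowered after 24 h. Of the raised genes, 128 were also raised over the 4 organs. In the root after 24 h, 122 of the 304 raised genes rose and 95 of the 380 lowered genes fell at least 2-fold. In the leaf positions the medians at 3 h stood at 0.32 for the raised and -0.1 for the lowered genes, against 1.52 and -1.31 at 24 h. These genes were chosen by their change at 24 h, so that the larger medians at that time follow largely from the selection. The changes of different leaf positions were correlated across genes, which are not independent replicates, at 0.022 to 0.08 at 3 h and at 0.258 to 0.379 at 24 h. Those of the root and a leaf position were correlated at -0.032 to 0.166 at 3 h and at 0.115 to 0.272 at 24 h. The 3 h and 24 h changes share the 0 h libraries. Their correlation across genes was 0.639, against 0.503 in simulated values without any change, with a covariance of 0.133 against 0.056. With the 3 h change taken in other organs than the 24 h change, no 0 h library was shared, and the correlation was 0.072 to 0.217. This also sets different organs against each other, over fewer libraries. The lower values can therefore not be put down to the shared libraries alone.

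**Figure D1:**
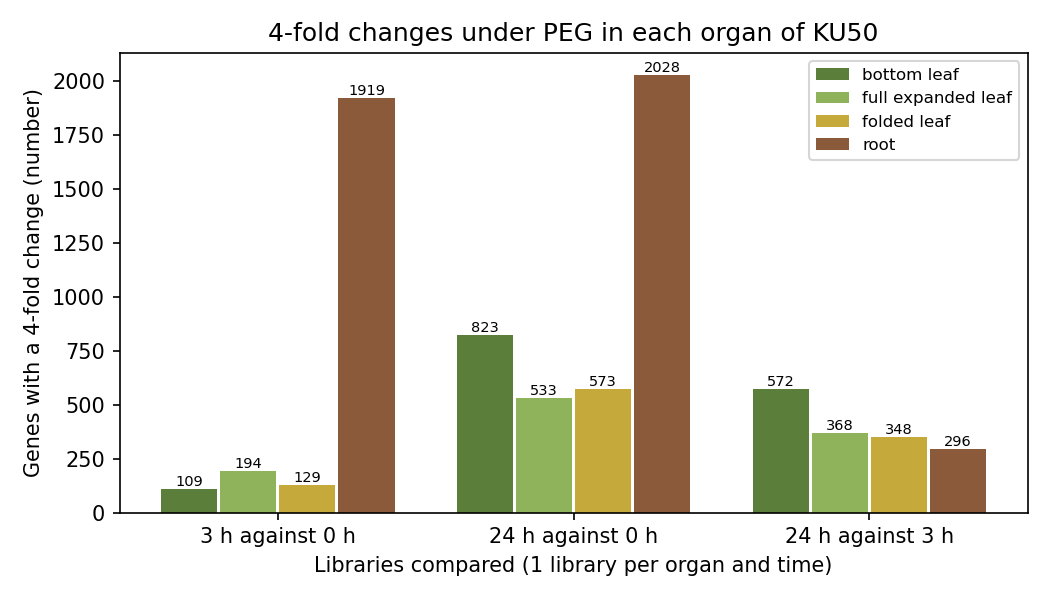
Number of genes with a 4-fold change (vertical axis) between 2 libraries of the same organ, for 3 pairs of times (horizontal axis); each bar is 1 organ. The root has 1919 such genes at 3 h against 109 to 194 in the leaf positions, and 296 between 3 h and 24 h.

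The changes from 0 h in the root differed from those in the leaves. In the test of that difference 1416 of 25942 genes passed (limma, moderated F test over both times). From 0 h, 1919 genes changed 4-fold in the root at 3 h and 2028 at 24 h, against 109 to 194 and 533 to 823 in the leaf positions. Between 3 h and 24 h the root had 296. Of the 1416 genes, 531 had at least doubled and 632 had at least halved in the root at both times. The gene cassava4.1_009575m.g stood at 18.4, 966 and 542 FPKM in the root at 0, 3 and 24 h and stayed between 0.216 and 0.933 in the leaves (limma adjusted p = 0.00142). The gene cassava4.1_022921m.g stood at 1766 and 29.9 FPKM at 0 h and 3 h, was listed at 0 at 24 h, and reached at most 2.157 in the leaves (limma adjusted p = 0.00142). The gene cassava4.1_019555m.g differed because of the leaves: it was at 2758 FPKM at 0 h and 34 at 24 h in the full expanded leaf and at 4.166 to 13.393 in the root. All changes from 0 h in the root rest on a single 0 h library, and an aberrant library was not told apart from a response. The root libraries leave no residual in this fit, so that its spread comes from the leaves alone. Genes near 0 in the leaves can therefore pass on a change in 1 root library. With a pseudocount of 0.1 the count was 242, after quantile normalization 2193, and leaving out the bottom leaf at 3 h gave 350.

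Groups of the organ series moved apart in the root. The median change of the stem-higher genes in the root was -0.91 at 3 h and -1.13 at 24 h, below all 10000 random lists of the same size matched on mean expression at both times. Both changes use the single 0 h root library, and random lists treat genes as independent. The rank therefore measures no spread between libraries. The difference from the leaves had a median of -1.07 at 24 h (camera adjusted p = 2.28e-16, and adjusted p = 0.338 with an estimated correlation). The storage-root-higher genes had medians of -0.31 and -0.53 in the root at 3 h and 24 h. The difference from the leaves was -0.47 at 24 h (camera adjusted p = 7.87e-08, and adjusted p = 0.305 with an estimated correlation). The leaf-higher genes had medians of 0.16 and 0.2 in the root.

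**Figure D2:**
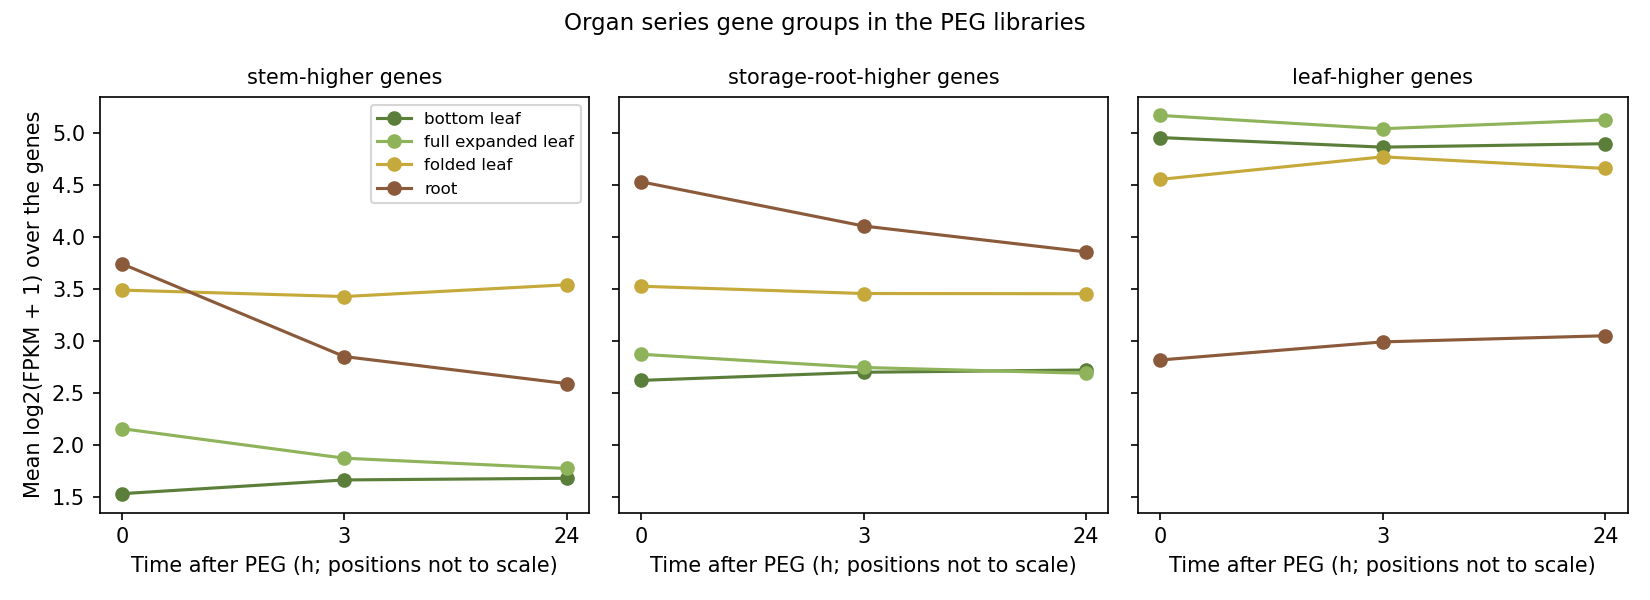
Mean log2(FPKM + 1) of 3 gene groups from the organ series (vertical axis) in the PEG libraries at 0, 3 and 24 h (horizontal axis, positions not to scale); each line is 1 organ and each point 1 library. In the root the stem-higher genes go from 3.741 to 2.849 and 2.589, and in the full expanded leaf from 2.156 to 1.872 and 1.773, while the folded leaf stays between 3.426 and 3.539.

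Between cultivars, 1401 genes were higher and 697 lower in Arg7 than in KU50, of 24689 tested with limma. The gene cassava4.1_022044m.g had 6960 ± 8520 FPKM in Arg7 and 69.1 ± 95.3 in KU50 (SD, n = 4 organs each, log2 difference 6.59 ± 0.57, SE, limma adjusted p = 0.00419). The gene cassava4.1_024010m.g had 4.61 ± 1.27 in Arg7 and 293 ± 112 in KU50 (SD, n = 4 organs each, log2 difference -5.65 ± 0.37, SE, limma adjusted p = 0.00358). After quantile normalization 890 were higher and 782 lower, and the median difference of all genes was -0.029, against 0.128 before. Among genes 2-fold apart, 57.8% were higher in Arg7 in the leaf, 49.6% in the early, 61.8% in the middle and 68.9% in the late storage root. The sums of FPKM values were 2165161 in the Arg7 leaf and 957249 in the KU50 leaf, but 766419 and 825453 in the early storage roots of Arg7 and KU50. The count of 2098 genes fell to 31 to 35 when a middle or late storage root library of either cultivar was left out.

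W14 differed from the other 2 cultivars in 8 higher and 7 lower genes, a comparison that rests on its leaf and stem. The gene cassava4.1_031236m.g had 7650 ± 7260 FPKM (SD, n = 2) in W14 and 149 ± 169 (SD, n = 3) in the other libraries of these organs (limma adjusted p = 0.0105). The count was 0 without the W14 leaf or the Arg7 leaf and 427 without the KU50 leaf. The W14 root, a single library, stood above the W14 leaf in the 60-day root-higher genes, with a median log2 difference of 1.13, and below it in the 60-day leaf-higher genes, with a median of -1.16. These medians lay outside the central range of random lists matched on mean expression, 0 to 0.07 and 0 to 0.05. Such lists measure no spread between libraries. In the same pair, genes higher in the folded leaf than in the bottom leaf had a median of 1.53, and genes lower there -0.98. Shifts of this size were therefore not particular to the 60-day root and leaf groups.

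No gene passed between late and early storage roots over the 2 cultivars, and 1069 of 24689 had an unadjusted limma p under 0.05. That is no more than the share of 0.05 that unchanged genes alone would give. On simulated values with 200 changed genes this comparison recovered none of 66 genes changed 8-fold, so that the count says little about stability. The cultivars had unequal numbers of 4-fold changes from early to late, 251 genes in KU50 and 2649 in Arg7, of which 1982 were higher in the late root of Arg7. The early storage root of Arg7 summed to 766419 FPKM and the late one to 2027897. From middle to late, which does not use the early libraries, there were 84 genes in KU50 and 479 in Arg7. Of genes with a 4-fold change in both cultivars, 33 moved the same way and 21 the opposite way. With 1 library per stage and cultivar, this difference was not tested.

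**Figure D3:**
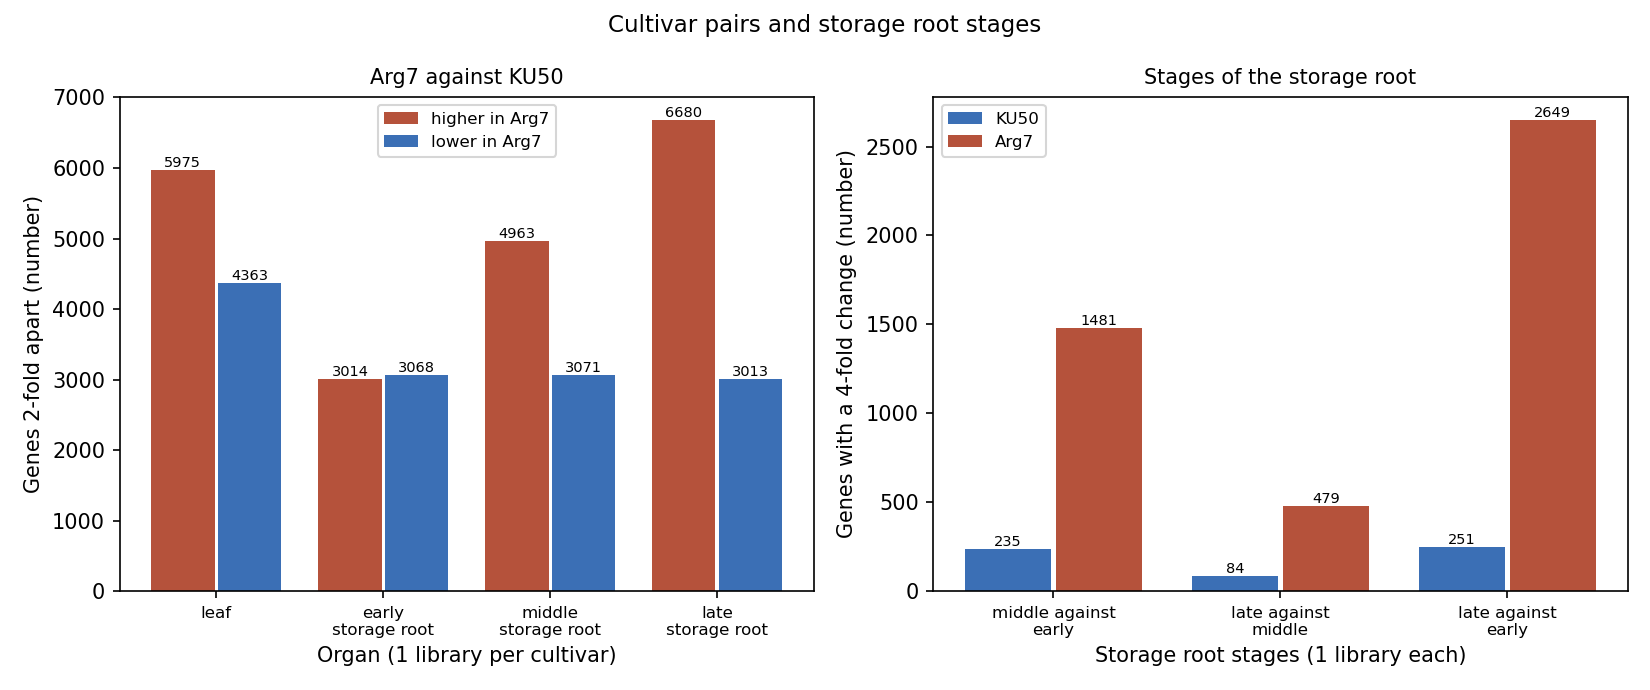
Left, number of genes 2-fold apart between the Arg7 and KU50 libraries of an organ (vertical axis) in 4 organs; right, number of genes with a 4-fold change between storage root stages in each cultivar. Higher and lower genes are even in the early storage root, 3014 and 3068, and Arg7 has 2649 changes from early to late against 251 in KU50.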

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

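The tests with another organ in place of the root, on genes at 10 or more in every library, with quantile normalization, with the ID-number trend removed, on the early storage root pair and with splits that keep the blocks were chosen after the result was seen. Among 15 sets of 4 PEG libraries (sum, median, genes of at least 1, genes at 0, share of the 10 most abundant genes) no library stood apart by Dixon's test. Each set held the 4 organs at 1 time, so that the 0 h root library was not compared with the other root libraries. The organ series was not tested in this way.

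The PEG response of the root differed from that of the leaves in 1416 genes by the test of the difference itself. PEG and the time since its start are not separated in these libraries. With a leaf position in place of the root, at most 1 gene passed. In those fits the root stays among the other organs and its changes widen the spread. A low count was therefore close to fixed in advance and decides little. There are 4 such choices, too few for a share under 0.05 (1 of the 4 gave as many genes as the root, the root itself). Low values stay open. Among genes with a mean of at least 10, 4.14% differed, against 5.46% of all genes, but that mean holds the root values, so that genes near 0 in the leaves pass, and the bound set beforehand was too weak. Among genes at 10 or more in every library 1.65% differed (128 genes), but that filter also leaves out large falls. A pseudocount of 0.1 gave 242 genes. Leaf tissue in the 0 h root library is argued against by the leaf-higher genes, whose median change from 0 h to 3 h was 0.16 and not a fall. The 0 h root library stays open too. The change from 3 h to 24 h, which does not use it, differed in 9 genes only. An aberrant 0 h library and a root response that was complete by 3 h and lasted cannot be told apart, because both leave little change after 3 h and there is 1 root library at 0 h.

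More genes were higher than lower in Arg7 against KU50, 66.8% of those that passed. Quantile normalization brought this to 53.2%, but it also centres the difference between the cultivars, so that it decides nothing, and a scaling difference between libraries stays open. A length trend stays open: after removal of a trend with the ID number 65.1% were higher, but the removal covers 65.8% of the genes tested, and the relation of the ID number to length was read from low genes alone, so that it decides nothing. In the early storage root pair, where the Arg7 sum is not the larger, 49.6% of genes 2-fold apart were higher in Arg7, against 62.8% in the other 3 pairs together. Of the 16 splits that keep the organs, 1 gave as many genes as the real one with 2098 (the real one itself), and 16 are too few for a share under 0.05. The highest other gave 490. It called the 4 KU50 libraries Arg7 and left only the Arg7 stem in place, so that it is the real split turned around and not an unrelated grouping. The remaining splits gave 0. Among 100 splits that need not keep the organs, the highest other gave 2324 and set the Arg7 early storage root apart from the other Arg7 libraries, together with the 4 KU50 libraries. That split still holds the KU50 libraries apart from the other Arg7 libraries, with both early storage roots on the same side. It is nearly the real split turned around, so that its count does not argue against the cultivar. A difference between Arg7 libraries may still be part of the pattern, and the cultivar itself stays open as untested.

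Genes at 0 in all 4 KU50 libraries of the organ series and at 1 or more in all 5 Arg7 libraries numbered 6. Of these 16.7% (1 gene, exact 95% interval 0.4% to 64.1%) were at 0 in all 12 KU50 libraries of the PEG series, against 0% of 120 matched genes. Low expression missed by chance and a difference in sequence or gene content cannot be told apart with 6 genes.

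The fits hold organs, times or cultivars as blocks, so each count from groups of at least 3 libraries was compared with the splits that keep the blocks (1 library of each organ, time or cultivar in a group). Other splits leave differences between blocks in the noise. A share under 0.05 was reached for root against leaves at 60 days only (1 of 64 as large). That comparison gave 8308 genes without organ terms, against 9590 in the reported model, and at most 2175 in the other splits. The root libraries are 1 organ at 3 times, so that the share shows that they resemble each other and does not exclude chance between plants. It was not adjusted for the number of comparisons, and this one was added after the data were seen. For the other comparisons of such groups the splits are too few for a share under 0.05. PEG 24 h against 0 h gave 283 genes and the highest other split 1 (1 of 8). PEG 24 h against 3 h gave 5 and the highest other 0 (1 of 8). PEG 3 h against 0 h gave 0, as did the other splits (8 of 8). Folded leaf against bottom leaf gave 6358 and the highest other 0 (1 of 4). Storage root against leaf, with stages as 1 organ, gave 8269 and the highest other 0 (1 of 16). W14 gave 15 and the highest other 2104 (2 of 6). That split took the Arg7 leaf and stem for W14 in exchange for the W14 leaf and stem, and with over 100 times the real count it points to a structure of the libraries, which was not resolved further; an exchange of the Arg7 leaf alone or of the Arg7 stem alone gave 0.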

How the results depend on the processing

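The removal of the ID-number trend, the comparison of root and leaves at 60 days and the gene group tests were chosen after the data were seen. Outside of leave-one-out, 55 of 72 recomputed counts stayed within 1.5 times their main value; where a cause is not given, the cause was not tested. A pseudocount of 0.1 moved PEG 24 h against 3 h from 5 to 13 genes and the root response from 1416 to 242. Without the filter on low values, PEG 24 h against 0 h went from 283 to 113, Arg7 against KU50 from 2098 to 895 and W14 from 15 to 3. Quantile normalization gave 109 genes for PEG 24 h against 0 h (81 raised, 28 lowered), 9 for PEG 24 h against 3 h and 2193 for the root response. It moved the higher and lower genes of the folded leaf from 4036 and 2322 to 3334 and 2984, and those of Arg7 from 1401 and 697 to 890 and 782. Without a fold minimum, root against leaves at 60 days rose from 9590 to 14640. Without a block, PEG 24 h gave 0 genes against 0 h and 0 against 3 h, stem against leaf 1314, Arg7 against KU50 536 and W14 256. The 3 leaf positions alone gave 684 and 486 genes for PEG 24 h against 0 h and 3 h. Storage root stages as 1 organ gave 77 for W14. With 1 organ or library left out (a lone library was assumed to vary like the others), the counts ran from 0 to 684 for PEG 24 h against 0 h, 0 to 486 for PEG 24 h against 3 h, 350 to 1378 for the root response, 655 to 3246 for stem against leaf, 31 to 2381 for Arg7 against KU50 and 0 to 427 for W14. Storage root against leaf ran from 5484 to 7587, folded leaf against bottom leaf from 5121 to 6722 and root against leaves at 60 days from 9032 to 9715. The root response could not be fitted without the 0 h root library. PEG 3 h against 0 h and late against early storage root gave 0 under all alternatives run. Of the named genes, 52 of 578 recomputed calls were lost and none changed sign. Of 41 gene group calls, 40 were lost with an estimated correlation. Leaving out libraries turned 2 group directions: the leaf-over-stem genes at PEG 3 h had medians from -0.037 (without the folded leaf) to 0.146, and the 60-day leaf-higher genes in W14 from -0.686 to 0.044 (without the W14 leaf). The gene lists fixed in advance were not run, and depth is unknown, so that low genes are limited by the pseudocount and filter alone.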

Other observations

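The test below was chosen after related overlaps had been seen. Genes that fell in the root under PEG relative to the leaves and by at least 2-fold at 24 h, the root-lowered genes, were more often higher than lower in stem and storage root in the organ series. Of 516 measured there, 174 were higher and 5 lower in the stem than in the leaf (median 1.21, camera adjusted p = 4.9e-16, and adjusted p = 0.133 with an estimated correlation), and 204 were higher and 22 lower in the storage root (camera adjusted p = 7.98e-09, and adjusted p = 0.229 with an estimated correlation). The root-lowered genes had a mean log2(FPKM + 1) of 1.119 in the W14 leaf, 1.615 in the KU50 leaf and 1.606 in the Arg7 leaf, against 5.236 in the 0 h root. Genes this low in the leaf can hardly be lower in another organ, so that these counts follow in part from the selection. A hypothesis is that transcripts shared by growing organs were lost from the root. It needs the root-lowered genes to be found among the young-leaf-higher genes, and 203 were shared, 1.91 times the number for independent lists. These groups come from the same PEG series, the overlap was nearly implied by the stem values, and the single 0 h root library carries the pattern, so the hypothesis stays untested in independent material.

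PEG-raised genes stood lower in the storage root than in the leaf in the organ series: of 153, 58 were lower and 9 higher (median -1.19, camera adjusted p = 1.86e-05, and adjusted p = 0.601 with an estimated correlation). Independent lists would share 24.5 lower and 23 higher genes.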
